A study of Mus musculus with 4 samples.

How the data were processed

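The samples were single-cell RNA sequencing libraries of live CD45.2-positive immune cells sorted from the brains of mice that carried GL261 tumours. There were 4 groups with 1 library each: WT and IFNaR-/- (KO) mice without treatment, sorted on day 20, and WT and KO mice given anti-PD1, an antibody that blocks the T cell checkpoint receptor PD-1, sorted on day 25. Anti-PD1 was injected at 200 ug per mouse on days 7, 11, 15 and 19. Per the labels, suspensions were pooled before the sort, sorted CD3+ and CD3- cells of the anti-PD1 groups were combined in equal parts, and the same 10x Genomics 5' kit was used for all libraries. The receptor segment ratios and barcode overlaps reported below go against a single kit and setting, which was not settled here. The number of mice in a pool is not given. The deposited values were raw counts of UMIs per gene and cell barcode, with no normalization. The file headers name Cell Ranger 3.1.0 for the untreated and Cell Ranger 7.2.0 for the anti-PD1 libraries, and the submitters' processing notes name the builds mm10 and GRCm38. Neither gives the settings for intronic reads or for calling cells. A gene's UMI count depends on both the end of the transcript that is read and the counting of intronic reads, so contrasts across libraries of different kinds carry that difference. The feature lists held 31053 and 32285 genes, and the 30406 with an identifier in all 4 were used, which took 99.5% to 99.9% of the UMIs of each library.

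Cells were read with Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Cells with at least 200 detected genes and at most 10% mitochondrial counts were kept. The mitochondrial limit was passed by 21.0% of barcodes in untreated WT, 24.2% in untreated KO, 0.693% in anti-PD1 WT and 3.29% in anti-PD1 KO. Doublets were scored with Scrublet in each library. Its automatic threshold marked at most 2 cells per library, so the top-scoring cells up to a nominal rate of 0.8% per 1000 barcodes were removed instead (281, 83, 722 and 594 cells). Clusters came from 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1.0, with 1.5 within the T cell and dendritic cell groups. Interferon-stimulated, cell cycle and receptor segment genes were left out of the clustering. The 53 clusters were named from marker genes of 19 cell classes. Clusters with no clear class were left unnamed, and mixed T and myeloid clusters were set apart. Migratory dendritic cells of the anti-PD1 pair and type 2 conventional dendritic cells of the untreated pair were not compared, because a cluster of each held more leading markers of another class than of its own.

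Counts were summed per library and class and scaled to CPM of the class total. The log2 ratio KO/WT used a pseudocount of 0.5 and genes with at least 50 UMIs in the pair. Classes with under 50 cells in a library were not compared. Gene values have exact Poisson intervals, and shares have exact Clopper-Pearson intervals. Where a library had 0 counts, the fold was computed against a floor of 3 counts and given as a lower bound. For a gene list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on expression, and was said to lie outside them below percentile 2.5 or above 97.5. Anti-PD1 against untreated was computed in the same way within each genotype. Because 1 library per group leaves no spread between replicates, no p-values were computed. Intron lengths and gene positions came from the GENCODE annotation of GRCm38.

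The groups, the comparisons, 26 gene lists, the rule for naming genes and most alternatives were set before the data were examined. Named genes were Ifnar1; in CD8 T, CD4 T, microglia and monocyte/macrophage classes, up to 3 members of each list with the same direction in both pairs, ranked by the smaller absolute log2 ratio (at least 50 UMIs in each pair); outside the lists, the 4 highest and 4 lowest genes at least 2-fold different in both pairs; the same 4 and 4 for anti-PD1 against untreated; and the 2 highest and 2 lowest by the difference between the pairs. Receptor segment, mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out of the parts that go beyond the lists. Genes named outside this rule, Ifnar2, Isg15 and Irf7 over all cells and the X and Y genes and strain genes of the closing section, were chosen after their values were seen. Mx1, Mx2, Clec7a, Aldoa and Nnt were not among the shared genes under those symbols. Alternatives were a stricter filter (at least 500 genes and at most 5% mitochondrial counts), no cell filter, doublets kept, each library clustered alone, a doubled resolution, interferon genes kept in the clustering, TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors in R 4.3.3, a mean over cells of equal weight, cells thinned to 1000 UMIs, a minimum of 10 UMIs or none, and Pearson in place of Spearman correlation. An adjustment of the log2 ratios for intron length was added after seeing the data. The method was tested on simulated counts, drawn from Poisson distributions around the pooled rates of each class with 200 genes planted 2- or 4-fold apart. Genes planted 4-fold apart were all found at least 2-fold apart in the right direction in each class and pair, and of those planted 2-fold apart 41.0% to 55.6% were. Among unchanged genes, 0.0579% to 0.452% came out at least 2-fold apart, and 95.2% to 96.0% of their intervals held the true value. The draws held counting error only, with no difference in kind or handling between libraries. These rates therefore check the computation and do not give the error to be met between real libraries. Figures were drawn with matplotlib 3.10.9.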

Results

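Immune cells from the brains of mice carrying GL261 tumours, a mouse glioma line implanted into the brain, were profiled by single-cell RNA sequencing in 4 libraries. There was 1 library for each combination of genotype and treatment. KO stands for IFNaR-/- mice, which lack the receptor for type I interferons, cytokines that switch on antiviral genes in most cell types. The untreated libraries were sorted on day 20 after implantation and the anti-PD1 libraries on day 25. The series describes its question as what blockade of the checkpoint receptor PD-1 does to immune cells when interferon signalling is missing. The deposited counts held 6662 barcodes and 48270410 UMIs for the untreated WT library, 3705 barcodes and 32410040 UMIs for the untreated KO library, 9530 barcodes and 94732545 UMIs for the anti-PD1 WT library, and 8764 barcodes and 54559749 UMIs for the anti-PD1 KO library. After filtering, 24334 of 28661 cells were kept, with a median of 7109, 9484, 8468 and 4962.5 UMIs per cell in the same order. With 1 library per group there was no spread between replicates to compare a difference with, so no test was made and each statement below describes these libraries. The anti-PD1 WT and KO libraries also differed in kind, with values given at the end of this section. Intervals are 95% and cover counting error only.

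Ifnar1, which encodes one subunit of the type I interferon receptor (chromosome 16, 91485238 to 91507441 on GRCm38), was read in every library. Over all cells its level was 97.46 (94.5 to 101) CPM (counts scaled to the library total) in untreated WT, 129.6 (125 to 134) in untreated KO, 77.3 (75.5 to 79.3) in anti-PD1 WT and 146 (143 to 149.5) in anti-PD1 KO. Ifnar2, the gene of the other subunit (chromosome 16, 91372783 to 91405589), stood at 91.0, 69.4, 298 and 204 CPM in the same order. The labels give neither the subunit nor the part of the gene that was removed, so these levels do not check the genotype. Genes downstream of the receptor separated the genotypes. Isg15, a ubiquitin-like antiviral protein, stood at 980.1 (971 to 989.7) CPM in untreated WT and 93.9 (90.4 to 97.55) in untreated KO, and at 1052 (1045 to 1059) and 58.3 (56.1 to 60.5) in the anti-PD1 libraries. Irf7, the transcription factor that amplifies interferon production, stood at 361 and 19.5 CPM without treatment and at 407 and 4.15 CPM after anti-PD1.

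Among T cells, the KO libraries held a larger share of CD8 T cells, which kill target cells, than the WT libraries. The share was 50.3% (47.7 to 52.9%) in untreated WT and 62.6% (58.8 to 66.3%) in untreated KO, and 40.3% (36.2 to 44.6%) and 65.1% (61.5 to 68.7%) after anti-PD1. Helper CD4 T cells made up 20.4% (18.4 to 22.6%) and 16.5% (13.8 to 19.6%) of T cells without treatment, and 29.2% (25.4 to 33.2%) and 17.9% (15.1 to 20.9%) after anti-PD1. Regulatory T cells, which restrain other T cells, made up 15.1% (13.3 to 17.1%) and 9.70% (7.55 to 12.2%), and 16.7% (13.7 to 20.2%) and 11.4% (9.12 to 14.0%). T cells that could not be named CD8 or CD4 made up 10.8% and 8.94% without treatment, and 13.8% and 5.62% after anti-PD1. They count in the total of T cells but in neither class. The CD8 T cells came from different clusters. In untreated WT, 373 of them lay in a cluster marked by Cd8a, Gzmk and Nkg7 that held 108 cells of untreated KO. After anti-PD1, 350 KO cells and 23 WT cells lay in a cluster marked by Styk1, Themis and Itga1, and 87 KO cells and 187 WT cells in one marked by Gzmf and Gzma. A further anti-PD1 cluster of 119 WT and 88 KO cells, marked by Prf1, Gzmk and Cd8a, was set apart as mixed T and myeloid. It is left out of all these T cell shares, which were not recomputed with it.

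Among the other named cells, microglia, the resident macrophages of the brain, made up 10.9% (9.85 to 11.9%) in untreated WT and 13.4% (11.9 to 14.9%) in untreated KO, and 16.1% (15.3 to 17.0%) and 36.5% (35.4 to 37.7%) after anti-PD1. Monocytes and macrophages made up 59.6% (58.0 to 61.3%) and 54.8% (52.6 to 56.98%) without treatment, and 81.5% (80.6 to 82.3%) and 61.5% (60.3 to 62.6%) after anti-PD1. In the untreated pair, natural killer cells made up 9.59% (8.63 to 10.6%) in WT and 4.36% (3.52 to 5.34%) in KO (0 and 1 cells after anti-PD1), and type 1 conventional dendritic cells, which cross-present antigen, 1.45% (1.08 to 1.90%) and 3.92% (3.12 to 4.86%). Under the stricter cell filter the untreated microglia share turned direction, with a log2 ratio KO/WT of -0.42 in place of 0.30. The log2 ratio of the natural killer share was -1.14, and -1.92 under the stricter filter and -0.69 with each library clustered alone. The clusters behind the monocyte/macrophage class differed by genotype. After anti-PD1, the WT cells lay mostly in a cluster marked by Ly6c2, Ly6i and Hp (3866 WT and 48 KO cells) and in one marked by Saa3, Apoc2 and Cfb (1929 and 56), while the KO cells lay mostly in a cluster marked by Retnla, Chil3 and Ccl8 (27 WT and 1750 KO cells) and in one marked by Fn1, Thbs1 and Arg1 (41 and 1598). Without treatment, a cluster marked by Vcan, Cxcl10 and Slfn4 held 921 WT and 158 KO cells, and one marked by Arg1, Chil3 and Fn1 held 1170 and 951.

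**Figure D1:**
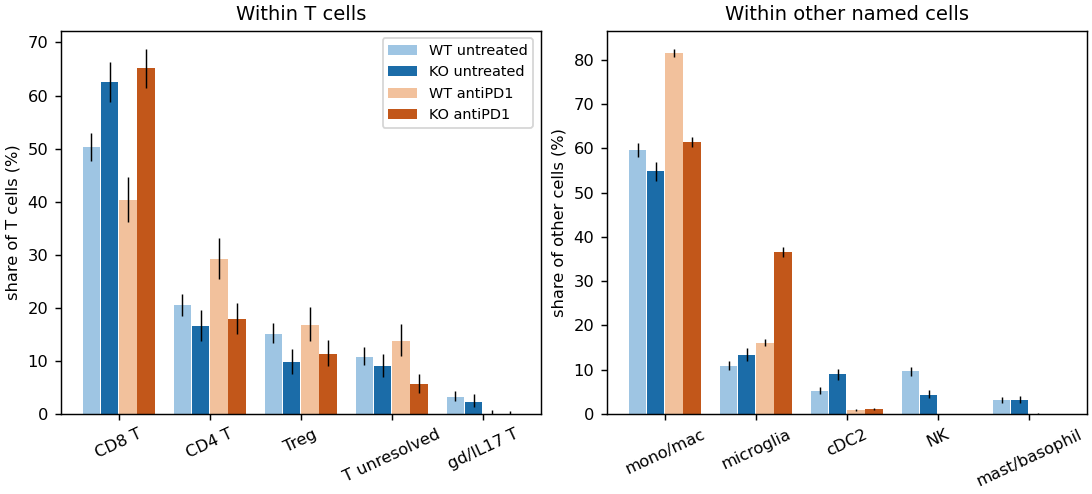
Shares of cell classes in percent, within T cells (left) and within all other named cells (right), for the 4 libraries; bars start at 0 and lines are exact 95% Clopper-Pearson intervals. CD8 T cells were 50.3% and 62.6% of T cells in the untreated WT and KO libraries, and microglia 16.1% and 36.5% of the other cells in the anti-PD1 WT and KO libraries.

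Interferon-stimulated genes, the set that type I interferon switches on, were lower in the KO library in each of the 17 comparisons that could be made (11 cell classes in the untreated pair and 6 in the anti-PD1 pair). The list's median log2 ratio KO/WT ran from -1.08 to -2.87, that is, 2.12- to 7.33-fold lower, and lay below all 10000 random lists matched on expression each time. Monocytes and macrophages gave -2.87 (-2.96 to -2.80) in the untreated pair and -2.75 (-2.88 to -2.63) in the anti-PD1 pair, with 71 of 71 and 71 of 71 measured members lower in KO. Microglia gave -2.16 (-2.39 to -2.07) and -2.75 (-2.95 to -2.53), with 62 of 63 and 69 of 69 lower. CD8 T cells gave -1.64 (-1.77 to -1.48) and -1.67 (-1.84 to -1.51), with 61 of 62 and 45 of 46 lower, and CD4 T cells gave -1.32 (-1.53 to -1.18) and -1.08 (-1.30 to -0.89), with 50 of 52 and 29 of 31 lower. Among the smaller classes of the untreated pair the medians were -2.43 in mast cells and basophils, -2.41 in neutrophils, -2.40 in plasmacytoid dendritic cells, -2.24 in type 1 and -1.84 in migratory dendritic cells, -1.43 in regulatory T cells and -1.28 in natural killer cells. In the anti-PD1 pair they were -1.58 in type 2 conventional dendritic cells and -1.31 in regulatory T cells. The type 2 cells of the anti-PD1 pair came from different clusters, with 64 WT and 5 KO cells in one marked by Plet1 and Ifi205, 8 and 31 in one marked by Cd209a and Tnip3, and 0 and 42 in one marked by Clec10a and Kit. The untreated type 1 cells did as well, with 33 WT and 11 KO cells in a cluster marked by Ifi205 and Rab7b and 18 and 69 in one marked by Xcr1 and Itgae. Of the natural killer cells, 275 WT and 44 KO lay in a cluster marked by Klra8 and Klra4, and 63 and 45 in one marked by Gzmc and Xcl1. Over all 215 values from the reported and the alternative settings, the median stayed between -3.06 and -0.89 and below all random lists. How much of the list in other classes was RNA carried over from monocytes and macrophages was not tested. Without treatment that class held Isg15 at 1968 CPM in WT and 126 in KO, and CD8 T cells held 136 and 25.7. RNA did cross classes, since 20.8% of untreated WT monocytes and macrophages had a UMI of Gzma, a natural killer marker.

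**Figure D2:**
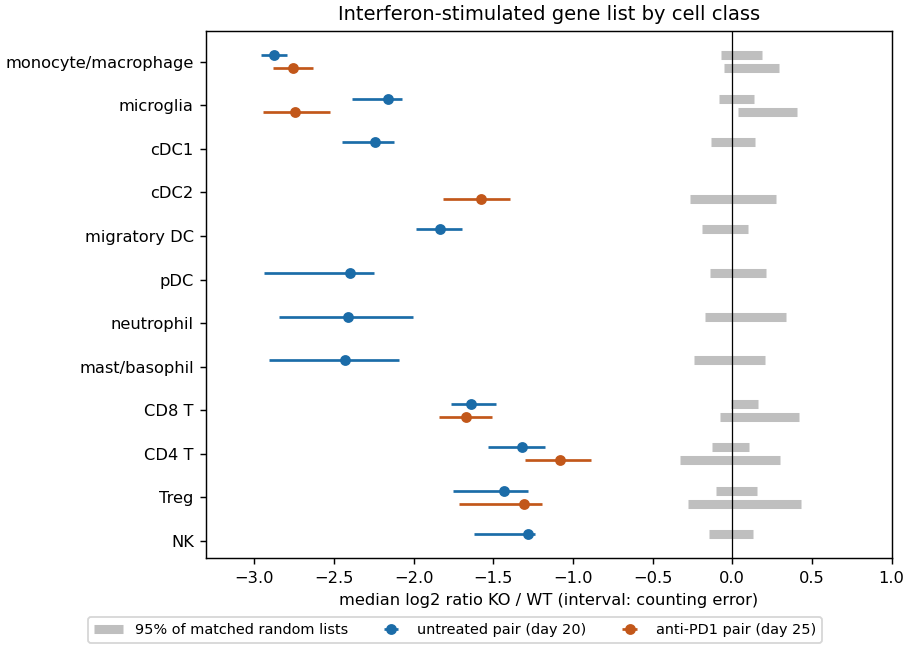
Median log2 ratio KO/WT of the interferon-stimulated gene list (horizontal axis) for each cell class (vertical axis); points are medians over measured genes with 95% counting intervals, blue for the untreated and orange for the anti-PD1 pair, and grey bars span 95% of matched random lists. The medians lie between -2.87 and -1.08, each to the left of its grey bar.

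In monocytes and macrophages, antiviral and MHC class I presentation genes were lower in the KO libraries, and genes of suppressive and wound-type macrophages were higher. After anti-PD1 the WT and KO cells of this class lay mostly in different clusters. Without treatment, 921 WT and 158 KO cells lay in a cluster with Cxcl10 among its leading markers. Retnla, Chil3 and Arg1 were leading markers of clusters made up mostly of KO cells after anti-PD1. No value of this class was recomputed within clusters, so a different mix of clusters and a change within cells were not told apart. Oas1g, which makes the activator of the antiviral nuclease RNase L, was 395-fold lower (95% interval 70.7 to 15647) in the KO library of the untreated pair and 339-fold lower (95% interval 116 to 1645) in that of the anti-PD1 pair. Ifit3, which binds viral RNA complexes, was 136- and 80.8-fold lower. Cxcl10, a chemokine that draws T cells, was 5.91-fold lower (95% interval 5.68 to 6.16) in the untreated pair (235 CPM in KO and 1389.5 in WT) and 5.32-fold lower (95% interval 5.15 to 5.50) in the anti-PD1 pair (160.1 and 851 CPM). Ccl24, a chemokine for eosinophils, was 11.7-fold higher (95% interval 11.4 to 12.1) and 38.3-fold higher (95% interval 37.0 to 39.6). The 28 measured IFN-gamma-linked genes had medians of -0.90 and -1.18, with 27 of 28 lower in each pair, and the 19 genes of MHC class I presentation -0.87 and -1.12, with 18 of 19 lower in each. H2-Q7, a non-classical class I molecule, was 4.51- and 5.40-fold lower.

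The inflammatory list had medians of -0.39 and -1.44, with 17 of 20 and 19 of 20 measured members lower in KO. Among them, Il12b, a subunit of the cytokine that drives type 1 helper T cells, was 5.24- and 2.90-fold lower, Il18 4.34- and 2.76-fold lower, and Acod1, which makes itaconate, 2.49- and 3.94-fold lower. The suppressive and wound-type list had medians of 0.50 and 0.58 (percentiles 99.99 and 99.71), with 14 of 20 and 17 of 22 higher. Chil3, a chitinase-like protein of alternatively activated macrophages, was 13.2- and 20.6-fold higher. Retnla, another product of such cells, was 58.8-fold higher without treatment and 8719.5-fold higher (2983 to 42289) after anti-PD1, where WT had 3 counts. Chil3 and the suppressive genes Arg1, Mrc1, Fn1, Tgfbi and Thbs1 were also among the markers that named the class. Genes of lipid handling in disease-associated microglia had medians of 0.29 and 0.56, and within them Lpl, lipoprotein lipase, was 3.59- and 12.9-fold higher and Spp1, osteopontin, 3.39- and 3.91-fold higher. The untreated lipid median kept its direction but lost its place outside the random lists when each cell weighed alike (0.31) or was thinned. Oxidative phosphorylation had medians of 0.28 and 0.55, and cell cycle 0.24 (percentile 91.5, inside the random lists) and 0.77 (percentile 100). Outside the lists, Slfn4, a Schlafen gene of myeloid cells, was 213-fold lower in KO without treatment and 1079-fold lower (194 to 42641, 1 count in KO) after anti-PD1, and Rnase2a, an eosinophil-type ribonuclease, was 46.5- and 400.2-fold higher.

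In microglia, interferon-stimulated and MHC class I presentation genes were lower in the KO libraries, and genes of suppressive and wound-type macrophages were higher. Cxcl13, a chemokine for B cells, was 144-fold lower (95% interval 39.5 to 1192) in the untreated pair, with 2 counts in KO, and 64.1-fold lower (95% interval 42.1 to 103) in the anti-PD1 pair. Oas1a was at least 44.0-fold lower without treatment, where KO had 0 counts, and 668-fold lower (185 to 5526, 2 counts in KO) after anti-PD1. Outside the lists, complement factor B (Cfb) was 21.1- and 50.4-fold lower, and Serping1, the complement C1 inhibitor, 5.33- and 15.2-fold lower. MHC class I presentation had medians of -0.77 and -1.24, with 18 of 19 and 19 of 19 lower, among them H2-Q7 (3.21- and 4.10-fold) and Psmb9, an immunoproteasome subunit (2.11- and 2.54-fold). IFN-gamma-linked genes had medians of -0.48 and -1.35, the first of which lay inside the random lists with thinned cells (-0.20). MHC class II presentation stood at 0.21 (percentile 92.5) without treatment and at -0.86 (percentile 0.0100) after anti-PD1, and at 0.16 and -0.73 in monocytes and macrophages. The difference between the pairs was not tested.

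The suppressive and wound-type list was higher in KO microglia, at 0.91 (percentile 100) without treatment and 0.62 (percentile 99.2) after anti-PD1. The second value lay inside the random lists with thinned cells or with no minimum count (0.50 in both). Ccl24 was 47.8- and 37.7-fold higher, Mrc1, the macrophage mannose receptor, 14.9- and 9.42-fold higher, and Arg1, arginase 1, 253-fold higher (69.5 to 2093, 2 counts in WT) without treatment and 9.76-fold higher after it. In the KO libraries these genes stood in microglia at 3.37% to 16.5% of their level in monocytes and macrophages. Macrophage RNA or cells among the microglia stay open as a source, with values given in the closing section. Homeostatic microglial genes had medians of -0.14 (percentile 2.10) and 0.25 (percentile 73.9), the first of which lay inside the random lists with thinned cells. Within that list Fcrls was 1.75- and 1.95-fold higher and Olfml3 1.44- and 2.39-fold lower. Cst7, a protease inhibitor of disease-associated microglia, was 2.13- and 2.93-fold lower, while Igf1, a growth factor, was 4.17- and 2.05-fold higher.

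In CD8 T cells, antiviral genes and MHC class I presentation were lower in the KO libraries. Rtp4, an inhibitor of viral replication, was 94.3-fold lower (95% interval 25.9 to 782) without treatment, with 2 counts in KO, and 186-fold lower (95% interval 32.8 to 7409) after anti-PD1, with 1 count. Ifi27l2a was 104- and 52.2-fold lower. The class I medians were -0.48 and -0.93, with 17 of 19 lower in each pair, and the IFN-gamma-linked medians -0.37 and -0.81. Nkg7, a protein of cytotoxic granules, was 1.67- and 2.02-fold lower, and Ccl5, a chemokine of effector T cells, 1.49- and 2.96-fold lower. The cytotoxic list as a whole stood at -0.04 (percentile 17.2) without treatment and at -0.96 (percentile 0, 19 of 21 lower) after anti-PD1. Adjusted for intron length, the second value was -0.44. After anti-PD1, 187 of 217 WT but 87 of 452 KO CD8 T cells lay in the cluster marked by Gzmf and Gzma. The CD8 T values were not recomputed within clusters, so a different mix of clusters and a change within cells were not told apart. Ly6c2, an effector and memory marker, was 10.2- and 9.09-fold lower.

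Genes of naive and memory T cells had a median of 0.91 (percentile 100) in untreated CD8 T cells and -0.04 (percentile 24.7) after anti-PD1. T cells of clusters with Tcf7, Lef1 and S1pr1 among the leading markers were named neither CD8 nor CD4 and lie outside this class. These clusters held 155 WT and 59 KO cells without treatment, and 73 and 39 after anti-PD1. The medians were not recomputed with them. Ccr7, the receptor that guides T cells to lymph nodes, was 4.19-fold higher in untreated KO and 35.1-fold higher (9.48 to 294, 2 counts in WT) after anti-PD1, and Bach2, a factor of memory cells, 2.20- and 3.11-fold higher. The regulatory T list stood at 0.69 and -0.10 in CD8 T cells, and within it Tnfrsf4, the costimulatory receptor OX40, was 3.25- and 1.61-fold higher. Exhaustion and checkpoint genes stood inside the random lists, at 0.08 and 0.04. Stress and heat shock genes, which tissue dissociation can raise, stood at 0.01 and -0.67 (percentile 0) and in monocytes and macrophages at -0.02 and -0.47. Interferon receptor and signalling genes (0.09 and 0.13), TGF-beta-linked and tissue residency genes (0.02 and 0.25), hypoxia and glycolysis (0.03 and 0.15) and chemokines (-0.09 and 0.14) lay inside the random lists in CD8 T cells. Genes near Ifnar1 on chromosome 16, which a line made in another strain would carry along, stood at 0.03 and 0.06, also inside them, and the substrain and passenger list stood at 0.20 and -0.14 in monocytes and macrophages, inside them as well.

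In CD4 T cells, Xaf1, which promotes cell death, was 5.05-fold lower (95% interval 2.92 to 9.46) in the KO library of the untreated pair and 9.29-fold lower (95% interval 3.47 to 35.0) in that of the anti-PD1 pair. Isg15 was 3.91- and 5.42-fold lower, and Bst2, tetherin, 3.84- and 4.87-fold lower. Areg, the growth factor amphiregulin, was 6.19-fold higher (95% interval 4.89 to 7.90) and 9.07-fold higher (95% interval 7.68 to 10.8), and Il2ra, the interleukin 2 receptor of activated and regulatory T cells, 1.86- and 1.84-fold higher. MHC class I presentation had medians of -0.37 and -0.59, with 19 of 19 and 16 of 19 lower. The second lay inside the random lists once adjusted for intron length (-0.19). Cell cycle genes stood at 0.51 and 0.66, and the untreated value turned to -0.07 when cells were thinned to equal depth.

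**Figure D3:**
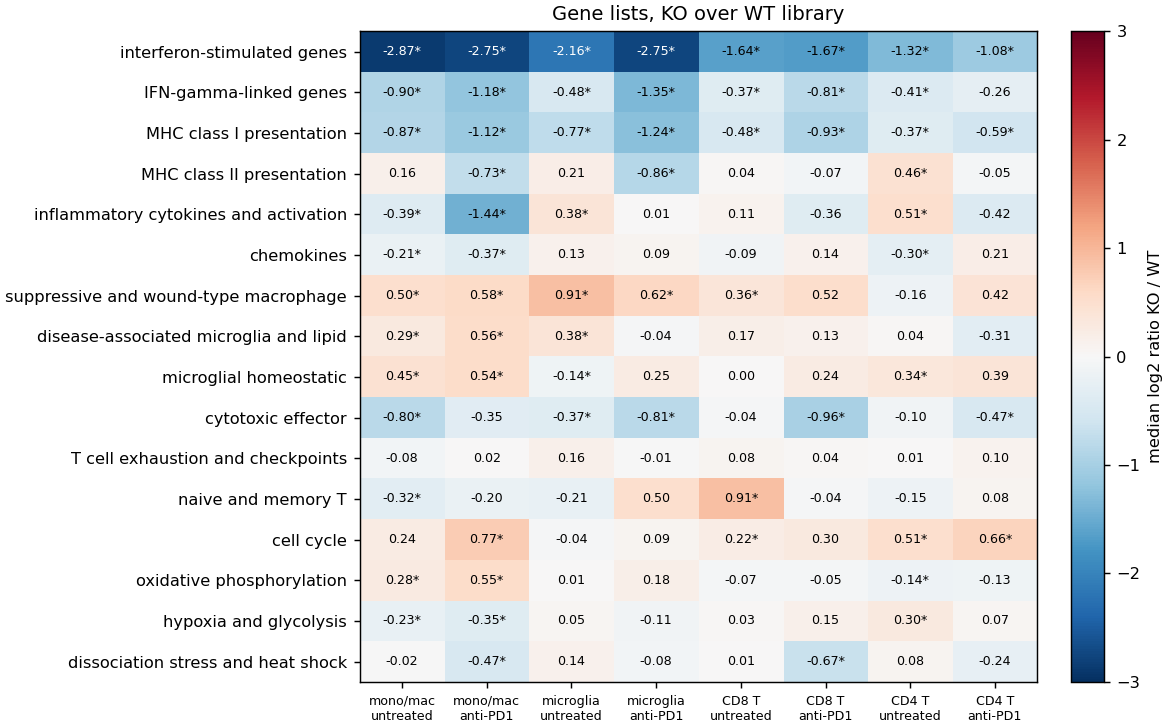
Median log2 ratio KO/WT (colour and printed value) of 16 gene lists (vertical axis) in 4 cell classes of the untreated and the anti-PD1 pair (horizontal axis); a star marks medians outside the central 95% of matched random lists. Interferon-stimulated genes are lowest in each column, from -2.87 to -1.08, and the suppressive list is above 0 in monocytes, macrophages and microglia.

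Both genotype pairs were compared gene by gene, which is the only repeat of the genotype contrast in separate libraries. Across genes, which are not independent replicates, the Spearman correlation between the log2 ratios of the pairs was 0.399 in monocytes and macrophages (10351 genes), 0.317 in CD8 T cells (6216), 0.268 in microglia (8570) and 0.0572 in CD4 T cells (4248). The 4 correlations were computed as one family, with no p-values. Over interferon-stimulated genes alone it was 0.912, 0.803, 0.895 and 0.644. At least 2-fold lower in KO in both pairs were 224 genes in monocytes and macrophages, where independent pairs would give 29.2, and 104 in microglia (8.19), 41 in CD8 T cells (2.95) and 20 in CD4 T cells (2.75). At least 2-fold higher in both were 215 (38.7), 61 (9.75), 31 (4.21) and 8 (2.03). Without the interferon-stimulated genes, those lower in both were 162 (22.6), 51 (5.08), 12 (1.20) and 6 (1.27) in the same order. With thinned cells the correlation was 0.123 in CD8 T cells, 0.123 in microglia and -0.0451 in CD4 T cells, and with each cell weighed alike -0.0560 in CD4 T cells. With no minimum count it was 0.178 in CD8 T cells. As Pearson correlations the values were 0.488 in CD8 T cells, 0.537 in microglia and 0.206 in CD4 T cells, and adjusted for intron length the CD4 T value was 0.0959.

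The anti-PD1 libraries differed from the untreated ones of the same genotype in the same direction for several groups, but not for all. In microglia, homeostatic genes such as those that name the class had a median log2 ratio (anti-PD1 on day 25 over untreated on day 20) of -1.11 in WT and -0.96 in KO, with 19 of 20 lower in each. The class was made of different clusters: untreated microglia lay almost wholly in one marked by Tmem119 and P2ry12 (373 WT and 269 KO cells), while 741 WT and 1279 KO cells of the anti-PD1 libraries lay in one marked by Apoc1, Lpl and Apoe and 289 and 881 in one marked by P2ry12 and Sparc. An untreated cluster of 16 WT and 10 KO cells marked by Lpl and Apoe had been left unnamed, few beside the 383 WT and 273 KO untreated microglia. The medians were not recomputed with it or within single clusters, so how far they follow the make-up of the class was not tested. Genes of disease-associated microglia stood at 0.63 and 0.83, and in monocytes and macrophages at 0.80 and 0.66. In CD8 T cells, cell cycle genes stood at -1.62 and -1.72, with 38 of 38 and 36 of 38 lower. In the untreated libraries 2 cycling clusters (111 WT and 90 KO cells, and 53 and 69) were named CD8 T. No T cell cluster of the anti-PD1 libraries had cycling genes among its leading markers. The medians were not recomputed without the cycling clusters, so fewer cycling cells and a change within the other cells were not told apart. Exhaustion and checkpoint genes stood in CD8 T cells at 0.72 and 0.65. MHC class II presentation stood at 1.13 in WT microglia (percentile 100) but at 0.19 in KO microglia (percentile 87.7), inside the random lists. In monocytes and macrophages it stood at 1.13 in WT and 0.42 in KO, the second at the edge of the random lists (percentile 97.51) and inside them with TMM factors. The same list stood at 1.97 and 2.07 in CD8 T cells, although these genes belong to antigen-presenting cells. The receptor gene Il31ra had 894 and 1048 UMIs in CD8 T cells of the anti-PD1 WT and KO libraries, and 1 and 0 in the untreated ones. Apoc2, an apolipoprotein, stood at 9.31 in WT and 8.53 in KO monocytes and macrophages on the log2 scale. Stress and heat shock genes, which sample handling can raise, were lower in the anti-PD1 libraries, at -0.81 and -1.22 in CD8 T cells, -0.64 and -1.20 in CD4 T cells, -0.71 and -1.83 in monocytes and macrophages (22 of 22 lower in KO), and -0.67 in KO microglia. In WT microglia they lay inside the random lists (-0.19). The median mitochondrial share of a barcode was 3.58% and 4.95% in the untreated WT and KO libraries and 0.615% and 1.77% in the anti-PD1 ones. Handling, treatment, day of sort, mixing of sorted cells, kind of library and version of the counting software are therefore not separable between these groups. The median over all genes was itself -0.34 in WT and -0.26 in KO microglia.

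The libraries also differed in kind. In T cells, UMIs of T cell receptor variable segments per UMI of constant segments stood at 0.0170 in untreated WT, 0.0146 in untreated KO, 2.07 in anti-PD1 WT and 0.0804 in anti-PD1 KO. These ratios go against the single kit that the labels name for all libraries, so a difference between libraries can come from how they were made. Between the anti-PD1 libraries the log2 ratio KO/WT went up with the summed intron length of a gene, with Spearman correlations across genes of 0.473 in CD8 T cells, 0.472 in CD4 T cells, 0.397 in microglia and 0.267 in monocytes and macrophages. In the untreated pair these were 0.135, -0.0370, 0.0445 and 0.0532. The median log2 ratio of all genes in the anti-PD1 pair was 0.20 in CD8 T cells, 0.23 in microglia and 0.12 in monocytes and macrophages.

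**Figure D4:**
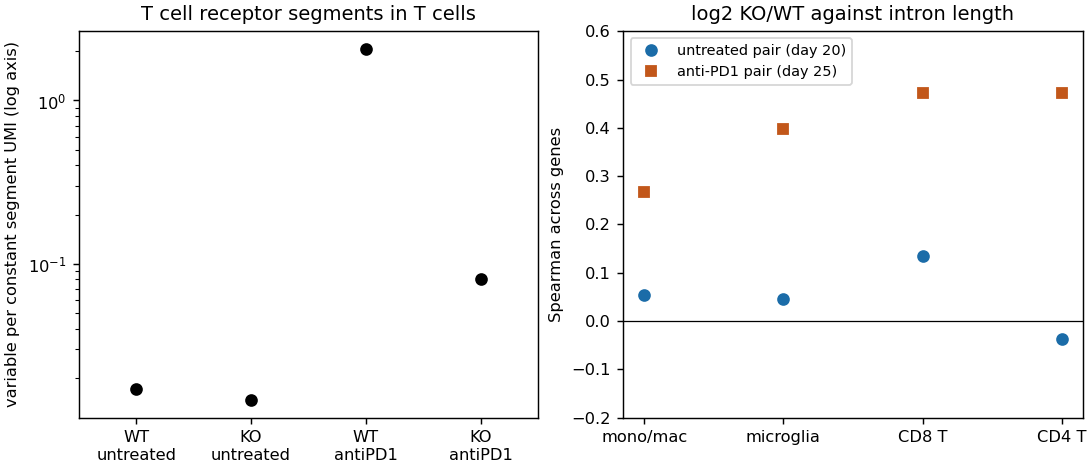
Left, variable per constant segment UMIs of T cell receptor genes in T cells of the 4 libraries (log axis). Right, Spearman correlation across genes between log2 KO/WT and summed intron length in 4 cell classes of both pairs; the anti-PD1 WT library stands at 2.07 on the left and the other libraries below 0.1, and the anti-PD1 pair lies above the untreated pair in each class on the right.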

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

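The genes below were picked because their log2 ratio KO/WT pointed one way in the untreated pair and the other way in the anti-PD1 pair, and none was followed up with a test. The difference between the pairs was not tested, since each rests on 1 library per group. Gzmc, a granzyme of activated killer cells, was higher in the KO library of CD8 T cells without treatment (log2 ratio 1.27) and lower after anti-PD1 (-3.75). Gzmd in CD4 T cells stood at 1.33 and -4.66, and the untreated value turned to -0.29 with thinned cells. Gzme in CD4 T cells stood at 2.11 and -3.68. Ifnb1, the gene of interferon beta, stood at 1.63 in untreated microglia, with 81 UMIs in KO and 33 in WT, and at -4.57 after anti-PD1, with 2 and 48. Lcn2, a neutrophil and macrophage protein that binds iron carriers, stood at 4.67 and -1.87 in monocytes and macrophages, where KO had 5 UMIs after anti-PD1.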

How the results depend on the processing

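Of 5809 values recomputed under the alternatives (4821 set beforehand and 988, the adjustment for intron length, chosen after the result was seen), 4097 stayed within the counting interval of the reported value, 1696 moved beyond it and 16 were counted as reversed. A change of sign was counted as reversed for list medians outside the random lists and genes at least 2-fold apart. It was also counted for share ratios whose interval left out equality and for all correlations. Any other change of sign is among the values that stayed or moved. The interferon-stimulated list stayed below all random lists in each of its 215 values, with medians from -3.06 to -0.89. Under some settings a class had under 50 cells or no clear name and gave no value: 13 of the 17 interferon-stimulated comparisons remained under the stricter filter and 15 with interferon genes kept in the clustering. The scalings, equal weights, thinning and count minimums were not run for natural killer cells and mast cells or basophils. A lower count minimum leaves named genes as they are, since their rule asks for 50 UMIs. In CD4 T cells 4248 genes passed the minimum in both pairs, against 10351 in monocytes and macrophages. The CD4 T class had 157 WT and 124 KO cells after anti-PD1, with median depths of 5262 and 3461.5 UMIs, against 6165 and 4261 monocytes and macrophages with 8804 and 4411 UMIs, and cell number and depth were not separated. Of the recomputed values, only the moved ones of the main shares, of selected lists in the main classes and of the correlations, and every value counted as reversed, follow by setting. They are given as log2 values or correlations, and the cause was not tested.

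Under the stricter cell filter, the log2 KO/WT ratio of shares was -0.42 (microglia, untreated) and -1.92 (NK, untreated), and the interferon-stimulated median was -1.97 (microglia, untreated). With each library clustered alone, the log2 KO/WT ratio of shares was -0.69 (NK, untreated), 1.40 (microglia, anti-PD1) and -0.32 (mono/mac, anti-PD1), and the interferon-stimulated median was -2.55 (mono/mac, anti-PD1). With doublets kept, the log2 KO/WT ratio of shares was 1.29 (microglia, anti-PD1) and -0.59 (mono/mac, anti-PD1), and the interferon-stimulated median was -2.39 (microglia, untreated), -1.82 (CD8, untreated) and -2.48 (microglia, anti-PD1). With no cell filter, the log2 KO/WT ratio of shares was -0.51 (mono/mac, anti-PD1). With each cell weighed alike, the MHC class I median was -0.65 (microglia, untreated), -1.17 (microglia, anti-PD1) and -1.22 (mono/mac, anti-PD1), and the interferon-stimulated median was -2.97 (mono/mac, untreated), -1.81 (CD8, untreated) and -2.42 (microglia, anti-PD1). The suppressive median was 0.59 (mono/mac, untreated) and 0.78 (mono/mac, anti-PD1), and the oxidative phosphorylation median turned to 0.00351 (CD4, untreated). The treatment contrast of MHC class II was 1.28 (WT microglia), 1.28 (WT mono/mac) and 0.50 (KO mono/mac), and the treatment contrast of cell cycle genes turned to -0.42 (KO mono/mac). The correlation of the pairs was 0.22 (CD8), -0.0560 (CD4), 0.21 (microglia) and 0.38 (mono/mac). With cells thinned to equal depth, the MHC class I median was -0.60 (microglia, untreated) and -1.20 (mono/mac, anti-PD1), and the suppressive median was 0.81 (microglia, untreated), 0.72 (mono/mac, untreated) and 0.50 (microglia, anti-PD1). The interferon-stimulated median was -2.98 (mono/mac, untreated) and -0.90 (CD4, untreated), and the cell cycle median turned to -0.0653 (CD4, untreated). The microglial homeostatic median turned to -0.16 (CD4, untreated), and the treatment contrast of MHC class II was 1.33 (WT microglia), 1.29 (WT mono/mac), 0.0231 (KO microglia) and 0.49 (KO mono/mac). The treatment contrast of cell cycle genes turned to -0.12 (KO mono/mac), and the correlation of the pairs was 0.12 (CD8), -0.0451 (CD4), 0.12 (microglia) and 0.31 (mono/mac). Single genes turned direction, at 0.0656 (Itsn1 in CD8, untreated), 0.24 (Wdfy1 in CD4, untreated), -0.29 (Gzmd in CD4, untreated), 0.0565 (Gbp9 in microglia, untreated), 0.54 (Il27 in microglia, untreated) and 0.18 (Cbr1 in microglia, untreated). With TMM factors, the interferon-stimulated median was -3.004 (mono/mac, untreated), -2.97 (microglia, anti-PD1), -2.91 (mono/mac, anti-PD1) and -1.85 (CD8, anti-PD1), and the MHC class I median was -1.002 (mono/mac, untreated), -1.47 (microglia, anti-PD1) and -1.27 (mono/mac, anti-PD1). The suppressive median was 0.37 (mono/mac, untreated), 0.39 (microglia, anti-PD1) and 0.43 (mono/mac, anti-PD1), and the treatment contrast of MHC class II was 1.64 (WT microglia), 1.43 (WT mono/mac), 0.49 (KO microglia) and 0.70 (KO mono/mac). With DESeq2 size factors, the interferon-stimulated median was -2.98 (mono/mac, untreated), and the MHC class I median was -0.98 (mono/mac, untreated), -1.40 (microglia, anti-PD1) and -1.23 (mono/mac, anti-PD1). The suppressive median was 0.39 (mono/mac, untreated), 0.46 (microglia, anti-PD1) and 0.47 (mono/mac, anti-PD1), and the treatment contrast of MHC class II was 1.56 (WT microglia), 1.41 (WT mono/mac), 0.49 (KO microglia) and 0.70 (KO mono/mac). With no minimum count, the suppressive median was 0.78 (mono/mac, untreated) and 0.50 (microglia, anti-PD1), and the interferon-stimulated median was -1.79 (CD8, untreated) and -2.14 (CD8, anti-PD1). The treatment contrast of microglial homeostatic genes turned to 0.95 (WT CD4), and the correlation of the pairs was 0.18 (CD8), 0.20 (microglia) and 0.27 (mono/mac). With interferon genes kept in the clustering, the interferon-stimulated median was -1.82 (CD8, untreated). With a minimum of 10 UMIs, the interferon-stimulated median was -1.79 (CD8, untreated) and -2.03 (CD8, anti-PD1), and the treatment contrast of microglial homeostatic genes turned to 0.27 (WT CD4). The correlation of the pairs was 0.27 (CD8) and 0.36 (mono/mac). At the doubled resolution, the interferon-stimulated median was -1.56 (CD4, untreated). Adjusted for intron length, the MHC class I median was -0.91 (microglia, anti-PD1) and -0.87 (mono/mac, anti-PD1), and the suppressive median was 0.72 (mono/mac, anti-PD1). The treatment contrast of MHC class II was 0.63 (KO mono/mac), and the correlation of the pairs was 0.28 (CD8), 0.0959 (CD4), 0.29 (microglia) and 0.42 (mono/mac). As Pearson correlations, the values for the pairs were 0.49 (CD8), 0.21 (CD4), 0.54 (microglia) and 0.58 (mono/mac).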

Other observations

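Of the tests in this part, those on free RNA, on the transcript end and intronic RNA within the anti-PD1 pair, and on macrophage RNA in microglia were chosen after the result was seen. Some groups of cells and genes belong to no comparison above. After anti-PD1, a cluster of 491 WT and 120 KO cells marked by Nos2, the inducible nitric oxide synthase, Nrg1 and Slfn4 matched no class. Interferon ligands came almost wholly from Ifng: the list summed to 199.5 CPM in untreated WT, 208 in untreated KO, 34.1 in anti-PD1 WT and 23.4 in anti-PD1 KO. Lung cell markers, included because the labels speak of lung cells, summed to 11.1, 83.8, 9.79 and 176 CPM, of which Ear2, an eosinophil-type ribonuclease that these macrophages also held, gave 73.4 and 159 in the KO libraries. Markers of GL261 and glial cells summed to 48.4, 51.0, 60.7 and 46.6 CPM, mostly Mbp, and red blood cell genes to 0.194, 0.348, 0.0602 and 0.209 CPM. Sex-linked genes, with Ddx3y of the Y chromosome highest in each library, summed to 209.9, 217, 149 and 191 CPM. T cells of all kinds made up 6.15% and 8.80% of the cells of the WT and KO anti-PD1 libraries, although CD3+ and CD3- cells were combined in equal parts.

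Of 3912 genes measured in the 4 main classes of both pairs, 4 were at least 2-fold higher in KO in each of the 8 comparisons and 12 at least 2-fold lower, 10 of which are in the interferon-stimulated list. The higher ones were Arhgap6 (chromosome X, 168795099 to 169304435), Hccs (X, 169250193 to 169320372) and Mid1 (X, 169685199 to 170005736), all within one stretch near the end of X, and Gm47283 (Y, 90784738 to 90816464). Just before that stretch, Msl3 had log2 ratios of at most 0.94. Prps2 passed 2-fold only in untreated monocytes and macrophages (1.33). Past Mid1, Gm21887 stood at 0.12 to 0.45 where measured. Asmt, further out, stood at 2.68 in microglia and 2.43 in monocytes and macrophages of the anti-PD1 pair, and was not measured elsewhere. One hypothesis is a DNA variant of the KO line that acts on nearby genes. The lowest Mid1 fold among the compared classes was at least 5.005, in untreated neutrophils with 11 UMIs in KO and 0 in WT. The lower limit there, 3.43, does not reach the 4-fold bound set for the hypothesis. In the other 16 comparisons the lower limit was 5.07 or more. Mid1 was picked for its rise in the 8 comparisons of the main classes, so only those of the other classes were new. A rise in every class would also follow from an effect of the receptor, so these folds do not favour a variant. Free RNA from a compared class is argued against, since the highest class level of Mid1 in a KO library was 1.43 times the median of the compared classes. A source outside these classes, such as unnamed cells, was not covered and would leave no such peak. A variant tied to the strain in which the line was made and a real effect of the receptor remain possible, and neither was tested.

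Large differences shared by all main classes also separated the libraries themselves, such as Il31ra and AC160336.1 between anti-PD1 and untreated. A different end of the transcript read in the anti-PD1 libraries may contribute, since the ratio of variable to constant receptor segments was at least 5.51 times higher there in both genotypes, and WT stood 25.8 times above KO within the anti-PD1 pair. A larger share of intronic RNA in the anti-PD1 KO library may contribute as well, since the correlation of log2 KO/WT with intron length was at least 0.267 in each of the 4 classes of that pair. Intronic reads counted in only the anti-PD1 libraries stay open, since the lowest of the 8 correlations was 0.0179 while others reached 0.460. Because these differences follow libraries, they cannot be told apart from treatment and day, and in the anti-PD1 pair not from genotype.

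Ccl24, Arg1 and Mrc1 were higher in microglia of the KO libraries, where macrophages held much of the same RNA. Macrophage RNA or cells among the microglia stay open: in the KO libraries the share of the macrophage level was at most 2.74 times the median share of other macrophage markers, within the bound of 3 that such carry-over needs, but Ccl24 stood at only 0.301 of it in anti-PD1 KO. The WT values point both ways: in untreated WT Arg1 had 497 CPM in macrophages and 0.580 in microglia, 0.0223 times the median share, compared with 1033 and 146 CPM in untreated KO, but in anti-PD1 WT it stood at 0.310 times that share (1792 and 44.3 CPM), and Mrc1 stood at 1.18 times it in untreated WT and 1.09 in untreated KO, as carry-over would give. Doublets stay open too: microglia with a UMI of these genes held 1.55 times the median UMIs of the others in untreated KO but 0.906 times in anti-PD1 KO, and after thinning 14.6% and 24.1% of KO microglia had such a UMI, against 2.63% and 3.36% in WT. A microglial response that needs loss of the receptor was not tested apart from these.

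Wdfy1 (chromosome 1), from the substrain and passenger list, stood at 0.285 to 0.910 times WT without treatment and 0.262 to 0.655 times after anti-PD1. The interval held 1 in 6 of the 17 comparisons (neutrophils, migratory and plasmacytoid dendritic cells, mast cells and basophils, and regulatory T cells of both pairs), and the untreated CD4 T value turned to 0.24 on the log2 scale with thinned cells. The neighbours of Ifnar1 as a list lay inside the random lists, but Sod1 (chromosome 16, 90220754 to 90226329) differed. It stood at 1.05 to 1.52 times WT without treatment and at 2.67 to 4.81 times after anti-PD1. The untreated intervals held 1 in neutrophils, type 1 and plasmacytoid dendritic cells, mast cells and basophils. The larger ratio after anti-PD1 went with a low WT level. In microglia WT had 189 CPM without treatment and 44.3 after anti-PD1, and KO 212 and 118. In monocytes and macrophages WT had 172 and 35.9, and KO 191 and 108. The anti-PD1 WT library also differed in kind, so these ratios cannot be assigned to the region around Ifnar1. Cbr1, another neighbour, stood at 0.321 to 1.12 times WT without treatment, with intervals below 1 in only microglia, CD8 T and CD4 T cells, and at 0.197 to 0.563 times after anti-PD1, where the interval held 1 in type 2 dendritic cells. The untreated Cbr1 value of microglia turned to 0.18 on the log2 scale with thinned cells. The barcodes of the anti-PD1 libraries overlapped in 95 cases and those of the untreated ones in 3, which corresponds to barcode sets of about 879168 and 8227570.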
